A study of Schistosoma mansoni with 12 samples.

How the data were processed

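RNA was sequenced from whole adult male Schistosoma mansoni, a blood fluke, of the Puerto Rican PR-1 strain at 49 days of age. Per the labels, each of the 12 samples pooled about 41 worms that had been kept for 18 hours with vehicle (1% DMSO), with S-praziquantel (S-PZQ, 0.5 µM) or with R-praziquantel (R-PZQ, 0.5 µM). Each group had 4 samples. Libraries were made with a stranded mRNA kit from 500 ng of total RNA and sequenced on an Illumina NextSeq 500. The labels name Trimmomatic 0.36, Bowtie2 2.2.9, RSEM 1.2.31, DESeq2 1.18.1 and edgeR 3.20.8 without tying them to steps, and the version of EBSeq and the genome build were not given in the sources used here.

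The authors deposited 6 tables, made with DESeq, EBSeq and edgeR for each enantiomer against the vehicle. Each table lists the RefSeq transcripts that passed and no others. The DESeq and edgeR tables of the authors hold counts per sample, rounded to whole numbers, and the EBSeq tables of the authors hold the unrounded expected counts. Where a transcript stood in both kinds of table, the counts differed by at most 0.5. The authors also deposited normalized values per sample, which are counts divided by 1 factor per library (a normalized score in the DESeq and edgeR tables and a normalized signal in the EBSeq tables), and the mean of the 8 normalized values. Each deposited table gives a log2 fold change and a fold change as a ratio. The DESeq and edgeR tables of the authors add a p-value, an adjusted p-value under 0.05 and a dispersion (the spread of a transcript between replicates). The EBSeq tables of the authors give PPDE, the posterior probability of a change as a fraction, which was at least 0.95. From rank and adjusted p, the authors' DESeq tests covered 6780 transcripts for R-PZQ and 5782 for S-PZQ, and their edgeR tests covered 9015 and 9059.

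Before the data were examined, it was fixed that the authors' DESeq table with an adjusted p under 0.05 would be the main result where no full count table was in hand, and the 21 gene lists, the rule for named genes and most alternatives were fixed then too. Of the 1928 transcripts listed in any table, 1928 were matched to a locus tag, on 1866 loci, and 668 of them (34.6%) carried no product name. Lists were matched on the product names of these 1928 transcripts, so members listed nowhere are not counted. In this way 365 transcripts fell in a list and 5 fell in more than 1. The locus tag Smp_246790, the channel known to be activated by R-PZQ, was not among the tags of the annotation and was not analysed here.

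For each transcript of the DESeq tables, group means and SDs (n = 4) were computed from counts divided by the authors' size factors. The log2 change was the log2 ratio of those means, with a standard error from a negative binomial model with the authors' dispersion. The Wald p of this model was checked against the deposited p, and the median ratio of their logarithms was 1.00. For a list, Fisher's exact test (two-sided) compared its rises and falls with those of the other called transcripts, with Benjamini-Hochberg adjustment over the lists that had called members (20 for R-PZQ, 19 for S-PZQ). A count adjusted over the list alone was not computed, because the p-values of members outside the tables were not analysed here. R-PZQ and S-PZQ were compared directly with the edgeR 4.0.16 quasi-likelihood test on the 264 transcripts listed in both comparisons by any tool, with the authors' size factors placed on 1 scale through the 4 vehicle libraries. The ratio of the vehicle factors between the comparisons ran from 1.121 to 1.125, a spread of 0.381%. The log2 ratio of R-PZQ over S-PZQ was that of edgeR. Its standard error came instead from the variances of the log2 normalized counts (plus 1) in the 4 R-PZQ and the 4 S-PZQ libraries.

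Named transcripts were, per comparison with the vehicle, the 8 largest rises and the 8 largest falls with a named product, an adjusted p under 0.05, a mean of at least 10 and the same direction in each table that listed them. Added to these were the 2 largest changes of each list with at least 3 called members. For R-PZQ against S-PZQ they were the 5 largest differences each way among transcripts called at least once and listed in both. This gave 47, 40 and 10 transcripts. Any other transcript named below was chosen after its values were seen.

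Library totals were not analysed here, since the tables hold part of each library. The listed counts per library ran from 2305257 to 3416144 in the R-PZQ tables and from 3532674 to 5289037 in the S-PZQ tables, and relative depth was read from the size factors. The transcripts called in the DESeq tables had a mean normalized count of at least 152.56 (R-PZQ) and 308.54 (S-PZQ). Within each group no pair of libraries was a copy of another over the transcripts called by DESeq, with a chi-square per degree of freedom of at least 30.7. Libraries of different groups were not compared in this way. PCR reads carry no molecular identifiers, so counting errors are lower limits of the error. The labels do not say whether the 4 samples of a group were separate cultures, so p-values of single transcripts measure the spread between these samples, which may be technical. Fisher's p-values of lists and the permutation p-values of neighbours and abundance take transcripts as units. They hold no spread between samples, and transcripts that move together by library are not independent, so these p-values may be too low.

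The steps were tested on simulated data. The refit of called transcripts found 65% of planted 1.5-fold changes and 98% of 2-fold changes at R-PZQ settings, and 82% and 98% at S-PZQ settings. It called 1.56% of unchanged transcripts at R-PZQ settings and 0% at S-PZQ settings. The refit was given the dispersion used to simulate, so these shares may be too favourable. The direct test found 73% of 1.5-fold and 91% of 2-fold changes, and called 0.333% of unchanged transcripts. The list test called 3.38% of lists with shuffled directions. Alternatives were the authors' edgeR and EBSeq tables, an adjusted p under 0.01, at least a 2-fold change, a minimum mean of 10, edgeR factors, a block for the sample number, each library left out in turn, DESeq2 1.42.0 for the direct test and vehicle libraries split between the comparisons. Transcripts listed in all 3 tables, relative depth as a covariate, the correlation without 1 extreme transcript or with split vehicles, the lists with libraries left out or in the EBSeq tables, and the intervals and exact tests of lists between the forms were added after seeing the data. All refits started from transcripts listed for passing, so their counts can fall and hardly rise. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 were used.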

Results

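Praziquantel, the drug used against schistosomiasis, has 2 mirror-image forms, of which the R form is the more active against the worm. The series asked how the transcripts of male worms differed after 18 hours with either form. It held 12 mRNA libraries, 4 each for vehicle, R-PZQ and S-PZQ. Relative depth, as the size factor on a common scale, was 1.03 ± 0.189 (SD, n = 4) for vehicle, 1.01 ± 0.111 for R-PZQ and 1.27 ± 0.155 for S-PZQ. By this measure vehicle replicate 2 was the shallowest library at 0.781 and S-PZQ replicate 2 the deepest at 1.45. Levels below are normalized counts as mean ± SD with n = 4, and log2 changes carry ± SE.

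The first comparison, R-PZQ against vehicle, asked which transcripts changed with the active form. The edgeR and EBSeq tables of the authors listed rises up to log2 5.48 and 8.82. Transcripts of small heat shock proteins, chaperones that bind unfolded proteins, had the highest rises among named products in their DESeq table. HspB1 (Smp_049240) went from 333 ± 213 to 2562 ± 494 (7.69-fold, n = 4), and the major egg antigen, a relative of the small heat shock proteins, went from 306 ± 161 to 2419 ± 241 (7.90-fold) in transcript XM_018794696.1 of Smp_049300.1. A second heat shock transcript, Smp_186020, rose 4.36-fold from 1084 ± 458 to 4725 ± 814, and the HSP20/alpha crystallin transcript Smp_049250 rose 2.82-fold from 5043 ± 1438 to 14209 ± 1847. Another transcript of the major egg antigen locus, XM_018794699.1, rose 3.61-fold from 932 ± 445 to 3369 ± 286. These 5 transcripts, from 4 loci, were the called members of 7 listed ones, and the summed level of the 7 rose from 7825 ± 2580 to 27839 ± 3316 (3.56-fold).

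Further rises under R-PZQ were those of an early growth response transcription factor (Smp_094930, from 332 ± 98.9 to 968 ± 39.5, 2.92-fold), of ubiquitin 1 (Smp_123260, from 816 ± 328 to 2381 ± 326, 2.92-fold), which encodes a tag for protein degradation, and of a fatty acid elongation enzyme (Smp_130370, from 108 ± 53.4 to 303 ± 152, 2.80-fold). The falls were smaller. A rab transcript, from a family of vesicle traffic regulators, fell from 1317 ± 268 to 547 ± 74.8 (Smp_129350, log2 -1.27 ± 0.19). A neurotransmitter transporter (Smp_160360) had a log2 change of -1.24 ± 0.26, bicaudal D-like protein (Smp_028070.1, XM_018794141.1) -1.24 ± 0.24, a nuclear hormone receptor (Smp_000340) -1.23 ± 0.31, and pericentrin (Smp_051510) -1.22 ± 0.19. The P-glycoprotein transcript Smp_170820, which encodes a drug efflux pump, fell from 475 ± 108 to 206 ± 47.6 (log2 -1.21 ± 0.26), and synaptotagmin (Smp_150350), a calcium sensor of vesicle release, fell from 597 ± 36.6 to 266 ± 21.9 (log2 -1.17 ± 0.17). In the authors' deposited DESeq table the adjusted p of the 8 largest rises ran from 3.65e-21 to 0.00674. A WD-repeat transcript (Smp_032800.1) was listed as the largest fall, yet its counts came from 2 vehicle libraries, at 1333 in replicate 2 and 942 in replicate 4, with 0 in the other vehicle and all R-PZQ libraries. The call of the elongation enzyme (Smp_130370) ended without R-PZQ replicate 2 (log2 1.08).

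Under R-PZQ, 906 transcripts were called in the authors' DESeq table, of which 426 rose, with a median of 1.53-fold, and 480 fell, with a median vehicle level 1.48 times the treated one. At least a 2-fold change was seen in 83, of which 54 rose and 29 fell. The 4 treated and 4 vehicle values did not overlap in 728 (80.4%), a share that listing itself favours. No product name was known for 306 (33.8%). The authors' edgeR table called 596 and all 3 tables shared 418, with 206 rises and 212 falls and no opposite direction.

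Of the 21 lists, 2 passed Fisher's exact test under R-PZQ after Benjamini-Hochberg adjustment. In the extracellular matrix list, 8 of 10 listed transcripts rose, 0 fell and 2 did not pass (adjusted p = 0.0425). The 8 were 7 collagen transcripts and matrix metallopeptidase-9 (Smp_162300), an enzyme that cleaves matrix proteins, which went from 285 ± 140 to 766 ± 135 (log2 1.43 ± 0.32). Collagen alpha-1(V) (Smp_170340) went from 3153 ± 954 to 6293 ± 481 (log2 1.00 ± 0.18). In the ribosomal protein list, 0 of 75 rose, 9 fell and 66 did not pass (adjusted p = 0.0425). Of these 9, 28S ribosomal protein S11 (Smp_129420, log2 -0.65 ± 0.20) and 30S ribosomal protein S2 (Smp_102840.1, log2 -0.58 ± 0.18) are organelle types, Smp_021760 is a ribosome assembly factor and the other 6 are cytosolic types. The call of Smp_129420 ended without vehicle replicates 2 or 4 (log2 -0.58 to -0.57) and that of Smp_102840.1 without vehicle replicates 3 or 4 or R-PZQ replicate 2 (-0.53 to -0.50). The call of the matrix list ended without R-PZQ replicate 4 (adjusted p = 0.0539) and without vehicle replicate 2 (0.0526) and in the authors' EBSeq table (0.204), though its 8 rises were the same in number. That of the ribosomal list ended in the authors' edgeR table (5 falls, adjusted p = 0.377), in their EBSeq table (1 rise and 0 falls), under 0.01 (0 falls), and without R-PZQ replicates 1 (0.319), 2 (0.134) and 4 (0.209) or vehicle replicates 2 (0.767), 3 (0.122) and 4 (0.925).

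No direction was called for the remaining lists under R-PZQ. In the DESeq table all called members rose in 4 of them. Gut proteases, which digest host blood, had 5 rises and 0 falls among 7 (adjusted p = 0.151), with cathepsin B (Smp_085010) going from 3042 ± 1617 to 5909 ± 322 (log2 0.96 ± 0.25) and hemoglobinase (Smp_075800) at 0.77 ± 0.19. Micro-exon genes, which encode secreted schistosome proteins, had 4 rises among 5 (adjusted p = 0.194), with MEG-13 (Smp_127990) at 1.00 ± 0.32 and MEG-8 (Smp_171190) at 0.94 ± 0.26. Stem cell and cell cycle transcripts had 4 rises among 15 (adjusted p = 0.194), with DNA topoisomerase I (Smp_033050.1, XM_018788713.1) at 0.91 ± 0.28 and ribonucleotide reductase (Smp_009030) at 0.47 ± 0.15. The female reproductive list had 2 rises among 12, both of them the major egg antigen transcripts above. Other tables differed: the female list had 3 rises and 3 falls in edgeR and 4 and 7 in EBSeq, gut proteases 3 rises in edgeR and 0 calls in EBSeq, stem cell transcripts 3 rises in edgeR and 7 rises and 1 fall in EBSeq, and micro-exon genes 4 rises in edgeR and 2 in EBSeq. The micro-exon rises were 2 without vehicle replicate 3 and 1 without vehicle replicate 4, and the stem cell rises 2 without vehicle replicate 3 or R-PZQ replicate 2. With 1 library left out, calls ended for MEG-13 without vehicle replicates 3 or 4 (log2 0.80 to 0.86), MEG-8 without vehicle replicate 4 (0.77), topoisomerase without vehicle replicate 2 (0.66) and ribonucleotide reductase without vehicle replicate 3 or R-PZQ replicate 2 (0.37 to 0.45).

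Other lists went both ways under R-PZQ. Heat shock and chaperones had 5 rises and 7 falls among 23, the rises being led by HspB1. Transcription factors had 14 rises and 7 falls among 36, with a zinc finger protein (Smp_044870) at log2 1.14 ± 0.21 and knotted-1 (Smp_146580) at 1.12 ± 0.35. These counts were 7 rises and 5 falls without vehicle replicate 2, and 9 and 5 without R-PZQ replicate 1. Tegument transcripts, from the worm's outer layer, had 10 rises and 8 falls among 29, with a dynein light chain (Smp_051400) at -1.04 ± 0.19 and a glucose transport protein (Smp_105410) at -1.03 ± 0.20. Proteasome and ubiquitin had 7 rises and 8 falls among 32, with proteasome subunit beta 2 (Smp_074500.1) at -0.77 ± 0.16. Muscle contraction had 5 rises and 3 falls among 27, with titin (Smp_163920) at 0.69 ± 0.19 and alpha-actinin (Smp_014780.1) at -0.62 ± 0.18. Lipid transport and metabolism had 5 rises and 3 falls among 15, with a marvel domain protein (Smp_044750) at -0.82 ± 0.16. In the EBSeq table the balance was reversed for heat shock (8 rises, 6 falls), tegument (5, 7), proteasome (9, 7) and lipid transport (1, 4). The call of knotted-1 ended without vehicle replicate 2 (log2 0.90) and that of alpha-actinin without vehicle replicate 2 or R-PZQ replicate 3 (-0.52 to -0.47).

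Calcium signalling had 2 rises and 4 falls among 15 under R-PZQ, but 1 rise and 1 fall without vehicle replicate 4. Its L-type calcium channel (Smp_124530) fell by 0.82 ± 0.24 on the log2 scale, from 3818 to 2166, while a 16 kDa calcium-binding protein (Smp_025380) was at -0.74 ± 0.16. Mitochondrial respiration had 2 rises and 7 falls among 22, with ATP synthase gamma (Smp_033670.1) at -0.64 ± 0.12 and cytochrome C1 (Smp_005290) at -0.61 ± 0.12. Its rises include a vacuolar ATP synthase subunit (Smp_079950, log2 0.30), which by name is not mitochondrial. Redox defence had 1 rise and 3 falls among 9, with thioredoxin Trx1 (Smp_008070) at -0.72 ± 0.16 and ferritin (Smp_087760), which stores iron, at -0.66 ± 0.15. Glycolysis had 1 rise, hexokinase (Smp_043030) at 0.42 ± 0.12, and 3 falls among 6, with glyceraldehyde-3-phosphate dehydrogenase (Smp_056970.1) at -0.38 ± 0.11. Neuronal signalling had 1 rise, a neuropeptide precursor (Smp_042120) at 0.93 ± 0.25, and 2 falls among 13. Solute carriers had 1 rise, a zinc transporter (Smp_069170) at 1.07 ± 0.26, and 2 falls among 9, with a mitochondrial carrier (Smp_055190) at -0.60 ± 0.19. Apoptosis had 1 rise and 2 falls among 4, with apoptosis stimulating protein of p53 (Smp_129670) at -0.43 ± 0.14 and an inhibitor of apoptosis (Smp_076370) at -0.32 ± 0.11. The multidrug transporter list had 1 fall among 3, the P-glycoprotein above, and 0 of 3 listed TRP channels were called in each of the DESeq, edgeR and EBSeq tables. These 3 channels entered the list through the S-PZQ EBSeq table alone, so their 0 calls under R-PZQ were set by that choice. In the R-PZQ EBSeq table rises outnumbered falls for neuronal signalling (6 and 2) and solute carriers (3 and 2). Leaving out vehicle replicate 2 ended the calls of glyceraldehyde-3-phosphate dehydrogenase (log2 -0.29), the mitochondrial carrier (-0.51) and the inhibitor of apoptosis (-0.28 to -0.32 over its 5 lost fits). The carrier was also lost without R-PZQ replicate 4 (-0.52) and the inhibitor without vehicle replicates 3 or 4 or R-PZQ replicates 1 or 4. Without R-PZQ replicate 2 hexokinase (0.33) was lost, without vehicle replicate 4 the calcium channel (-0.58), and without either of these 2 libraries Smp_129670 (-0.41 to -0.36). For the 18 tested lists without a call the adjusted p ran from 0.151 to 1.

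**Figure D1:**
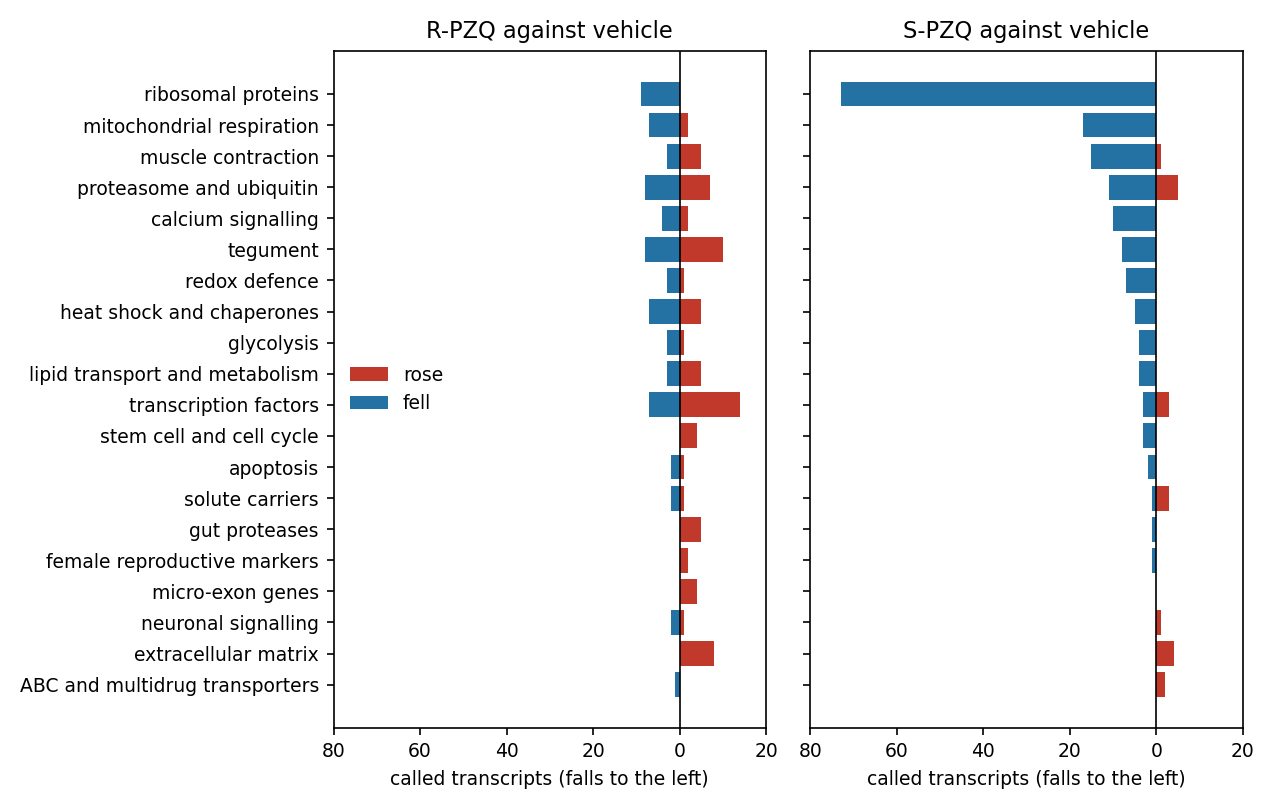
Number of called transcripts that rose or fell under R-PZQ and S-PZQ in each list with called transcripts, in the authors' DESeq tables. The TRP channel list, with 0 called in both comparisons, is not drawn. The ribosomal protein list had 73 falls under S-PZQ and 9 under R-PZQ, and the extracellular matrix list had 4 and 8 rises.

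The second comparison, S-PZQ against vehicle, asked the same of the less active form. Falls made up most of the changes, and ribosomal protein transcripts were the largest group, with 73 of 75 listed transcripts lower. 40S ribosomal protein S27 (Smp_041650) went from 4106 ± 1271 to 2057 ± 320 (n = 4) and 40S ribosomal protein S30 (Smp_014650) from 15904 ± 4088 to 8412 ± 2060 (log2 -0.92 ± 0.20). A calcium-binding protein, CaBP2 (Smp_025390), fell from 635 ± 297 to 136 ± 50.2 (log2 -2.23 ± 0.39). A saposin, of a lipid-binding family (Smp_130100), went from 67508 ± 13028 to 31650 ± 3994 (log2 -1.09 ± 0.15), and a surface membrane antigen (Smp_195180) from 30152 ± 6786 to 14230 ± 3557 (log2 -1.08 ± 0.20).

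Other large falls under S-PZQ were those of the cholesterol carrier NPC2 (Smp_194840, log2 -1.01 ± 0.26) and of bicaudal D-like protein, Smp_028070.1, in transcripts XM_018794143.1 (-1.14 ± 0.28) and XM_018794141.1 (-1.06 ± 0.36). The edgeR and EBSeq tables of the authors listed rises under S-PZQ up to log2 4.34 and 5.69. In their DESeq table the rises were small. A cadherin, an adhesion protein (Smp_125510), went from 274 ± 56.3 to 578 ± 208 (2.11-fold), a cell adhesion molecule (Smp_024660) from 482 ± 148 to 886 ± 65.1 (1.84-fold), and ubiquitin 1 (Smp_123260) from 917 ± 368 to 1549 ± 300 (1.69-fold). A zinc finger protein (Smp_018170) rose 1.78-fold, a ribonuclease III (Smp_142510.1) 1.75-fold, a tyrosine kinase (Smp_173380) 1.66-fold, a receptor tyrosine phosphatase (Smp_130570) 1.66-fold and the deubiquitinase USP9X (Smp_153690) 1.65-fold. In the authors' deposited DESeq table the adjusted p of these rises ran from 0.00221 to 0.0347. With 1 library left out the calls of ubiquitin 1 (log2 0.59 to 0.75) and XM_018794141.1 (-1.07 to -0.91) each ended in 6 of 8 fits, those without replicates 2, 3 or 4 of vehicle or S-PZQ. The zinc finger protein was lost without replicates 2 or 4 of either group (0.68 to 0.75), the tyrosine kinase (0.58 to 0.64) and USP9X (0.59 to 0.63) without vehicle replicates 2 or 4, XM_018794143.1 without vehicle replicate 2 (-0.80) and NPC2 without vehicle replicate 4 (-0.70). The 2 largest listed falls rested on few libraries. The WD-repeat transcript (Smp_032800.1) was at 639 ± 759 with vehicle, again from replicates 2 and 4, and at 0.666 ± 1.33 with S-PZQ. An eggshell protein (Smp_191910), a female product, was at 3097 in vehicle replicate 1 and between 8.64 and 372 in the other vehicle libraries, against 39.6 ± 26.0 with S-PZQ, with a log2 change of -1.78 without vehicle replicate 1. Both missed the threshold in the refit with all libraries too, so the fits with 1 library left out say nothing more about them. The summed level of the 7 eggshell and tyrosinase transcripts listed in both comparisons was 6202 in vehicle replicate 1 and 1059 in vehicle replicate 3, and between 26.1 and 247 in the other libraries.

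**Figure D2:**
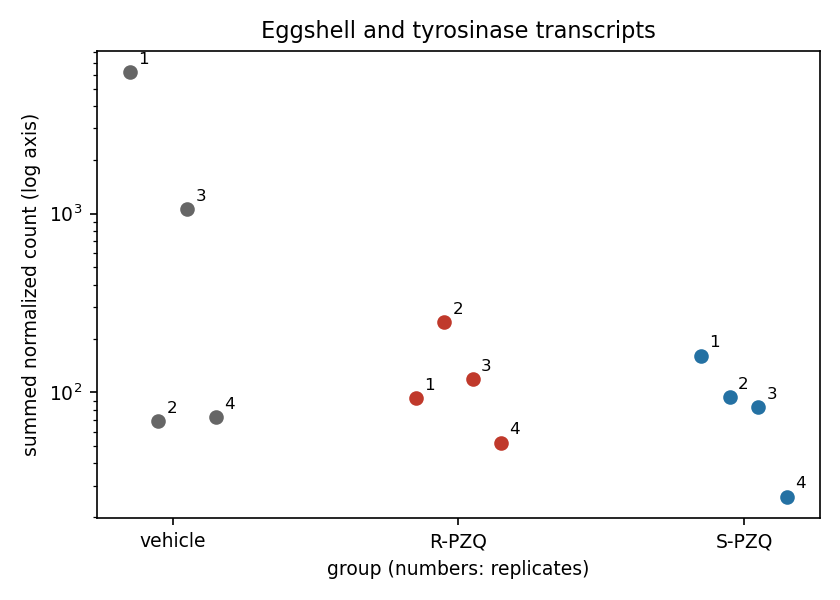
Summed normalized counts of the eggshell and tyrosinase transcripts on a log axis, with 1 point per library and its replicate number. Vehicle replicate 1 was at 6202 and vehicle replicate 3 at 1059, above the R-PZQ mean of 128 and the S-PZQ mean of 90.7.

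Under S-PZQ, 644 transcripts were called in the authors' DESeq table, of which 125 rose, with a median of 1.42-fold, and 519 fell, with a median vehicle level 1.44 times the treated one. At least a 2-fold change was seen in 15, with 2 rises and 13 falls. Treated and vehicle values did not overlap in 492 (76.4%), which listing again favours. No product name was known for 215 (33.4%). The share of rises differed by tool, at 19.4% in DESeq, 15.2% in edgeR and 42.7% in EBSeq. At least a 2-fold change was seen in 22 edgeR calls (5 rises, 17 falls) and in 94 EBSeq calls (48 rises, 46 falls). The 202 transcripts shared by all 3 tables had 37 rises and 165 falls with no opposite direction. By their size factors the S-PZQ libraries were deeper on average than the vehicle libraries. Listed counts, mostly of fallen transcripts, ran from 3532674 to 4596218 with S-PZQ and from 3726290 to 5289037 with vehicle. A change in RNA composition can also shift size factors, by which the counts were divided, so a fit on them cannot separate it from depth. With relative depth as a covariate 118 of the 644 passed (10 rises, 108 falls), with the sign unchanged in all 644. The median log2 change went from 0.51 to 0.37 for the rises and from -0.52 to -0.39 for the falls while standard errors grew 1.26 times, so calls ended by both smaller changes and larger errors. The authors' edgeR table called 356, and the number fell to 387 without vehicle replicate 2 and to 422 without vehicle replicate 4.

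In the S-PZQ comparison 2 lists passed Fisher's exact test. For the ribosomal proteins, 0 rose, 73 fell and 2 did not pass (adjusted p = 1.21e-06), with a median log2 change of -0.56, at most -0.36 in each, and no overlap of replicates in 53. Between the libraries closest in depth, vehicle 1 and 3 against S-PZQ 1 and 4, the median was -0.24, though these vehicle libraries also had the high eggshell sums above. The falls were 56 in the edgeR table, 19 in the EBSeq table, 52 under 0.01 and 47 without vehicle replicate 2, and the list was called in each of these (highest adjusted p = 0.0189). Relative depth moved with this group, at 1.03 ± 0.189 for vehicle and 1.27 ± 0.155 for S-PZQ (SD, n = 4), and with depth as a covariate 3 of the 73 passed and the list was not called (adjusted p = 1). For the extracellular matrix, 4 of 10 rose and 0 fell (adjusted p = 0.0130). These were laminin (Smp_143680), a basement membrane protein, at log2 0.68 ± 0.16, collagen (Smp_170340) at 0.64 ± 0.20, and a further laminin and collagen. The call of Smp_170340 ended without vehicle replicates 2, 3 or 4 or S-PZQ replicates 2 or 4 (log2 0.54 to 0.61). The matrix call ended in the edgeR table (2 rises, adjusted p = 0.128), in the EBSeq table (1 rise, 0.605), under 0.01 (1 rise, 0.417), with depth as a covariate (0 rises) and without S-PZQ replicates 2 (0.493) or 4 (0.155) or vehicle replicates 2 (0.484), 3 (0.577) or 4 (0.459).

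**Figure D3:**
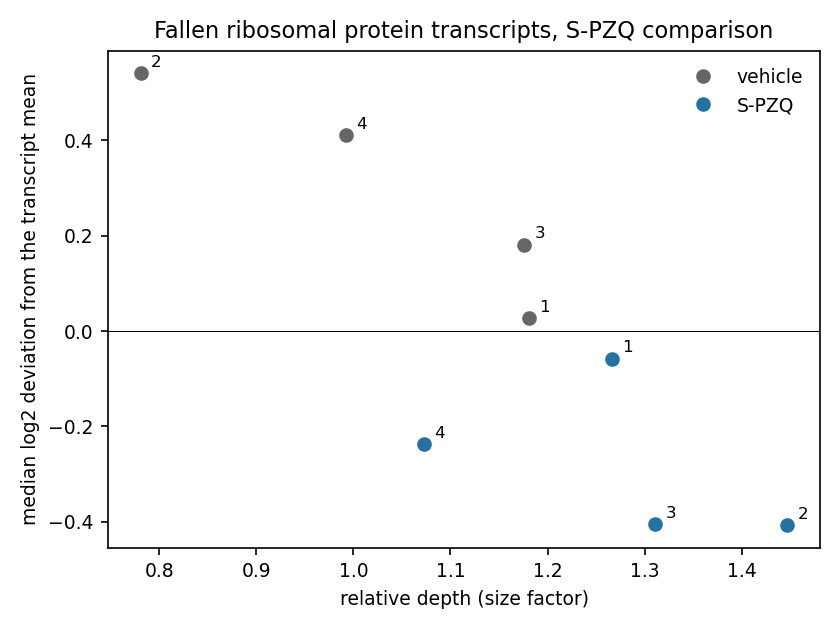
Median log2 deviation of the 73 fallen ribosomal protein transcripts from their mean over the 8 libraries, against relative depth (size factor), with 1 point per library and its replicate number. Relative depth averaged 1.03 for vehicle and 1.27 for S-PZQ.

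In the DESeq table all or nearly all called members of several lists fell under S-PZQ, while many members did not pass. With 519 falls among 644 calls, no direction was called for them against the other calls. Mitochondrial respiration had 17 falls and 0 rises among 22 (adjusted p = 0.208), with ATP synthase gamma (Smp_033670.1) at log2 -0.77 ± 0.13 and a subunit of cytochrome c reductase (Smp_024120) at -0.71 ± 0.13. Its falls include a vacuolar ATP synthase subunit (Smp_023160, log2 -0.60), which by name is not mitochondrial. Muscle contraction had 15 falls and 1 rise among 27 (adjusted p = 0.578), with alpha-actinin (Smp_046130) at -0.76 ± 0.16 and actin (Smp_161930) at -0.68 ± 0.14. Calcium signalling had 10 falls and 0 rises among 15 (adjusted p = 0.470), led by CaBP2, with the 16 kDa calcium-binding protein (Smp_025380) at -0.86 ± 0.16. Redox defence had 7 falls among 9, with ferritin (Smp_087760) at -0.85 ± 0.15 and thioredoxin Trx1 (Smp_008070) at -0.80 ± 0.17. Tegument had 8 falls among 29, with a dynein light chain (Smp_095520) at -0.70 ± 0.18 and the antigen Sm13 (Smp_195190) at -0.62 ± 0.18. Heat shock and chaperones had 5 falls among 23, with a chaperone binding protein (Smp_010160) at -0.58 ± 0.15 and a groES chaperonin (Smp_097380) at -0.54 ± 0.15. Glycolysis had 4 falls among 6, with glyceraldehyde-3-phosphate dehydrogenase (Smp_056970.1) at -0.47 ± 0.12 and lactate dehydrogenase (Smp_038950) at -0.42 ± 0.10. Lipid transport had 4 falls among 15, led by NPC2, with a lipid-binding ATP synthase subunit (Smp_000880.1, XM_018795211.1) at -0.49 ± 0.15. With depth as a covariate fewer falls passed, namely 5 for respiration, 12 for muscle, 4 for calcium signalling, 2 for redox defence, 1 for tegument, 0 for heat shock, 2 for glycolysis and 1 for lipid transport. In the edgeR table the falls were 10, 4, 7, 5, 4, 2, 0 and 2 in the same order, and in EBSeq they were 11, 9, 6, 5, 4, 2, 2 and 0, with 2 rises each for muscle, calcium signalling and heat shock and 1 for tegument. Respiration was called in the EBSeq table alone (adjusted p = 0.0312). Calls ended for this ATP synthase subunit without vehicle replicate 2 or S-PZQ replicates 3 or 4 (-0.45 to -0.38), Sm13 without vehicle replicate 2 or S-PZQ replicate 3 (-0.51 to -0.43), the groES chaperonin without vehicle replicate 2 (-0.38) and NPC2 without vehicle replicate 4 (-0.70).

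Smaller groups under S-PZQ were stem cell and cell cycle with 3 falls among 15, with DNA polymerase epsilon (Smp_036920) at log2 -0.43 ± 0.16 and delta (Smp_076660) at -0.34 ± 0.10, and apoptosis with 2 falls among 4. Gut proteases had 1 fall among 7, the saposin, and the female reproductive list 1 fall among 12, the eggshell protein. Proteasome and ubiquitin had 5 rises and 11 falls among 32, with a ubiquitin fused to ribosomal protein L40 (Smp_089430) at -0.86 ± 0.19, but 5 rises and 6 falls in the edgeR table, 9 and 2 in the EBSeq table and 0 and 1 with depth as a covariate. Transcription factors had 3 rises and 3 falls among 36, with a TFIIH subunit (Smp_052760) at -0.58 ± 0.19. Solute carriers had 3 rises and 1 fall among 9 (adjusted p = 0.156), with a cationic amino acid transporter (Smp_123010) at 0.59 ± 0.17 and a potassium-chloride cotransporter (Smp_198430) at 0.52 ± 0.17. Multidrug transporters had 2 rises among 3 (adjusted p = 0.178), neuronal signalling had 1 rise among 13, and 0 of 5 micro-exon genes were called in each of the DESeq, edgeR and EBSeq tables. The 5 micro-exon genes entered the list through the R-PZQ tables alone, so their 0 calls under S-PZQ were set by that choice. Micro-exon genes listed nowhere are not counted. The 3 TRP channels of the list were called in neither the DESeq nor the edgeR table and rose in the EBSeq table. They entered the list through that table alone, so TRP channels listed nowhere are not counted. DNA polymerase epsilon missed the threshold in the refit with all libraries. With 1 library left out calls ended for the TFIIH subunit without vehicle replicate 4 or S-PZQ replicate 3 (-0.55 to -0.46) and for the cotransporter without vehicle replicates 3 or 4 or S-PZQ replicates 1 or 2 (0.45 to 0.49). In the edgeR table stem cell transcripts had 0 calls, the female list 2 falls, solute carriers and multidrug transporters 1 rise each and transcription factors 1 rise and 1 fall. In the EBSeq table stem cell transcripts had 2 rises and 5 falls, the female list 8 falls, gut proteases 1 rise and 1 fall, neuronal signalling 4 rises, solute carriers 2 rises and transcription factors 5 rises and 2 falls. With depth as a covariate 0 stem cell, solute carrier, multidrug transporter and transcription factor transcripts passed. For the 17 tested lists without a call in the DESeq table the adjusted p ran from 0.156 to 1.

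The third comparison set the mirror-image forms against each other at the same dose and time. The ryanodine receptor (Smp_163570), a channel that releases calcium from internal stores, was at 39179 ± 2209 with R-PZQ, 20390 ± 1608 with S-PZQ and 31551 ± 2492 with vehicle (log2 R over S 0.94 ± 0.07, n = 4). One titin transcript (Smp_157010), for a large muscle protein, was at 7132 ± 482, 3997 ± 136 and 5744 ± 609 (0.84 ± 0.05), and tubulin beta (Smp_030730) at 76430 ± 11731, 43807 ± 5506 and 58771 ± 7170 (0.80 ± 0.14). A protein kinase (Smp_142620) went the other way, at 184 ± 18.2 with R-PZQ, 419 ± 33.5 with S-PZQ and 312 ± 28.4 with vehicle (log2 -1.19 ± 0.09).

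Of 264 transcripts listed in both comparisons, 24 differed between the forms in edgeR's quasi-likelihood test at an adjusted p under 0.05, with 13 higher and 11 lower under R-PZQ. The 2 forms moved 9 of the 24 in opposite directions from the vehicle, and 19 lay farther from the vehicle under R-PZQ. The largest differences included transcripts without a known product, namely Smp_172460 (3779 ± 370 with R-PZQ, 1794 ± 260 with S-PZQ, log2 1.08 ± 0.13), Smp_146720 (6846 ± 1903 and 15753 ± 844, -1.20 ± 0.22), Smp_057410 (435 ± 33.8 and 915 ± 131, -1.07 ± 0.12) and Smp_152960 (281 ± 65.0 and 533 ± 60.6, -0.92 ± 0.21). The edgeR adjusted p of the 8 named transcripts that differed ran from 0.000121 to 0.00462. The eggshell protein (Smp_191910, log2 0.91 ± 0.75, edgeR adjusted p = 0.542) and the WD-repeat transcript (Smp_032800.1, at 0 with R-PZQ and 0.592 with S-PZQ, edgeR adjusted p = 0.684) did not pass. Because listing favours transcripts with a small spread within each group, these p-values and standard errors may be too low.

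**Figure D4:**
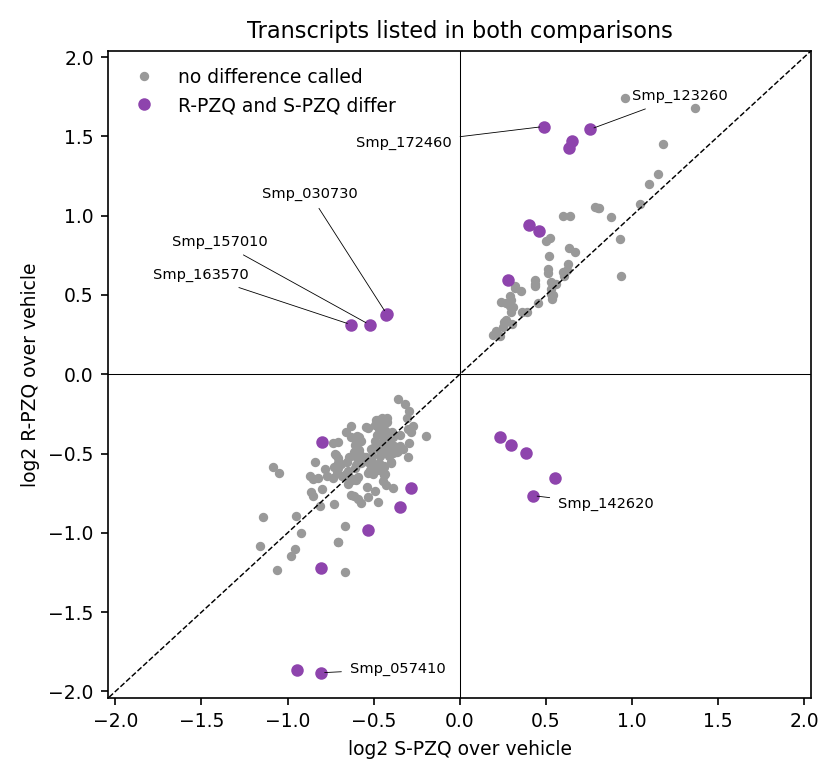
Log2 change from vehicle under S-PZQ (horizontal) and R-PZQ (vertical) for 234 of the 264 transcripts listed in both comparisons, with the 23 that differ between the forms in purple and equal change on the dashed line. Another 30 transcripts, 1 of them different, lay beyond a log2 change of 2 or at 0 and were left out, and the ryanodine receptor (Smp_163570), titin (Smp_157010) and tubulin beta (Smp_030730) were above vehicle with R-PZQ and below it with S-PZQ.

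For most transcripts listed in both comparisons no difference between the forms was called, and the median absolute log2 ratio was 0.132. For 6 lists with at least 4 such transcripts the mean log2 level per library was compared, which was chosen after the data were seen. An exact permutation test could call no single list after adjustment, because its smallest p of 0.0286 becomes 0.171. For 8 ribosomal protein transcripts R-PZQ minus S-PZQ was 0.14, with a 97.1% interval from -0.23 to 0.42, given by the differences between single libraries. The interval ran from -0.16 to 0.39 for 6 respiration transcripts (difference 0.16), from -0.04 to 0.64 for 5 calcium signalling transcripts (0.24), from -1.56 to 0.64 for 4 redox transcripts (-0.19) and from -0.90 to 1.79 for 7 female reproductive transcripts (0.18). For 8 proteasome and ubiquitin transcripts it ran from 0.00131 to 0.174 (0.08), with this smallest exact p. The small heat shock transcripts were in no S-PZQ table, so their S-PZQ levels were not analysed here. If they were tested there with the spread seen under R-PZQ, a rise of HspB1 (Smp_049240) beyond 1.83-fold and of Smp_186020 beyond 1.58-fold under S-PZQ would have been listed.

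Both forms shared 179 called transcripts, of which 28 rose with both, 145 fell with both and 6 went in opposite directions. This was 27.8% of the S-PZQ calls and 19.8% of the R-PZQ calls. Independent lists would have shared 8.45 rises and 41.6 falls. Since both comparisons used the same vehicle libraries, unchanged groups were simulated against them for the 1371 transcripts called at least once. Of these, 0.0598% were called in both, which scales to 3.46 calls in 5782 tests. The simulated spread was set for each transcript, and whether library shifts common to many transcripts would raise this count was not tested. With 2 vehicle libraries for each comparison, 38 to 61 transcripts were called in both. Across the 179 transcripts, which are not independent replicates, Pearson's r of the log2 changes was 0.931 and Spearman's rho 0.691. Without the WD-repeat transcript (Smp_032800.1) r was 0.882 (covariance 0.277), and with the vehicle libraries split r ran from 0.644 to 0.811, in transcripts called against all 4. Simulated unchanged groups had an r of 0.485 and a covariance of 0.0169. Their transcripts were not chosen for being called in both, so this is no reference for the observed r.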

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

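The tests on the ribosomal proteins, the eggshell transcripts and the small heat shock transcripts were chosen after the result was seen, and the splits of the samples were planned before.

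Of 190 groups of 4 values behind the named transcripts, 10 held a sample far from the other 3, where chance gives about 1 in 20 groups, or 9.5 here. Vehicle replicate 1 was that sample in 4 of the 10. It had HspB1 (Smp_049240) at 652 against 206 to 239 in the other vehicle libraries, hemoglobinase (Smp_075800) at 81976 against 41552 to 45330, 28S ribosomal protein S11 (Smp_129420) at 1161 against 2163 to 2339, and the eggshell protein (Smp_191910) at 3097 against 8.64 to 372. Glyceraldehyde-3-phosphate dehydrogenase (Smp_056970.1) was at 172419 in vehicle replicate 2 against 136315 to 141519, and the TFIIH subunit (Smp_052760) was at 534 in vehicle replicate 3 against 659 to 676. In S-PZQ replicate 1 the WD-repeat transcript (Smp_032800.1) was at 2.66 against 0, and collagen (Smp_170340) was at 3953 against 5827 to 6202. NPC2 (Smp_194840) was at 1225 in S-PZQ replicate 2 against 2140 to 2178, and the protein kinase Smp_142620 was at 211 in R-PZQ replicate 2 against 174 to 176.

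The direct edgeR test of R-PZQ over S-PZQ found a difference for 8 named transcripts. On the log2 scale these were 1.08 for Smp_172460, 0.94 for the ryanodine receptor (Smp_163570), 0.84 for titin (Smp_157010) and 0.80 for tubulin beta (Smp_030730), and -1.20 for Smp_146720, -1.19 for the kinase Smp_142620, -1.07 for Smp_057410 and -0.92 for Smp_152960. Among the 35 splits of the 8 treated libraries into groups of 4, 1 split, the real one, gave as many as 24 transcripts, and the highest other gave 1, but listing favours a small spread within each real group. For each comparison with the vehicle 1 of 35 splits, the real one, reached the real count, with 898 transcripts against a highest other of 313 for R-PZQ and 638 against 394 for S-PZQ. All 3 counts leave chance open, because the transcripts were listed for passing in the real groups, so the limit of 5% of the splits set before was wrong for them.

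Ribosomal protein transcripts fell under S-PZQ, in libraries that by their size factors were also deeper on average than the vehicle libraries. Size factors can also shift with RNA composition, which was not told apart from depth. A single vehicle library as the cause is argued against by the median log2 ratio, which stayed at or below -0.47 without any 1 of them, although vehicle replicates 2 and 4, the shallowest, lay highest (deviations 0.54 and 0.41, against 0.03 and 0.18). Depth stays open: with relative depth in a linear fit over the 8 libraries the difference went from -0.57 (SE 0.15) to -0.35 (SE 0.12), and 3 of 73 transcripts passed in place of 73, in part because standard errors grew 1.26 times, and libraries of closer depth (vehicle 1 and 3, S-PZQ 1 and 4) had a median of -0.24, though vehicle 1 and 3 also had the high eggshell sums. A vehicle group that stands apart from both treated groups and an effect common to both forms cannot be told apart, because the 8 fallen transcripts with a median R over S log2 ratio of 0.14 were chosen by being listed under R-PZQ, and 7 of the 65 in no R-PZQ table lay beyond their R-PZQ bound, which the choice of large falls favours. An effect of S-PZQ itself may add to either, and was not tested apart from them.

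Eggshell and tyrosinase transcripts, made in the female reproductive system, stood out in vehicle replicate 1, although the labels describe males. The summed level of the 7 listed in both comparisons there was 6202, against 1059 in vehicle replicate 3, 69.1 and 72.6 in the other vehicle libraries, 128 ± 83.9 with R-PZQ and 90.7 ± 55.1 with S-PZQ (SD, n = 4). Reads moved among these 7 transcripts are argued against, because their sum was 5.86 times that of the next highest library. Reads from related transcripts that were not listed were not analysed here. RNA of female tissue in this library is a candidate source, and no biological explanation was tested. That 7 of 8 listed transcripts were highest in it restates the observation and does not bear on the source. Of the rest of the female list, the major egg antigen transcripts are also related to small heat shock proteins.

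The rise of small heat shock and major egg antigen transcripts under R-PZQ came from 4 loci that lie within 13 consecutive genes of the annotation. Reads moved among the 7 listed heat shock and egg antigen transcripts are argued against by their summed level. In the lowest R-PZQ library it was 3.09 times the vehicle mean. The sum does not cover related transcripts that were not listed, so reads from those stay open. A single library is argued against, since 5 of 5 called transcripts passed without any 1 library, with a lowest log2 change of 1.36. Female tissue is argued against only as far as it carries the listed eggshell and tyrosinase transcripts. Their highest sum with R-PZQ was 0.233 times that of vehicle replicate 3 and lower still against replicate 1. Every heat shock sum with R-PZQ was at least 2.09 times those of these vehicle libraries. The eggshell and tyrosinase transcripts were listed for differing from the vehicle, which can favour a low sum with R-PZQ, so female tissue without them stays open. Eggs stay open, since their RNA need not hold much of the eggshell transcripts, whose sum with R-PZQ was 0.319 times that of vehicle replicates 2 to 4 but 1.80 times that of vehicle replicates 2 and 4, without the high replicate 3. A response of the worms to R-PZQ was not tested apart from eggs or from the other sources left open here.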

How the results depend on the processing

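The results in transcripts shared by all 3 tables, with depth as a covariate, for lists with a library left out or in the EBSeq tables, and for the correlation without 1 transcript or with split vehicles were chosen after the result was seen. The 906 R-PZQ calls became 596 in the edgeR table, 438 under an adjusted p of 0.01, 83 with at least a 2-fold change and 418 in all 3 tables; fewer pass by construction in the last 3, and for edgeR the cause was not tested. The 644 S-PZQ calls became 356, 315, 15 and 202 in the same settings and 118 with depth as a covariate, where standard errors grew 1.26 times. Leaving out 1 library gave 614 to 831 calls for R-PZQ, and 387 (without vehicle replicate 2) to 609 for S-PZQ, with 422 without vehicle replicate 4. EBSeq (1010 and 609), edgeR factors (894 and 636) and depth for R-PZQ (885) stayed within 1.5 times, and a minimum mean of 10 removed 0 transcripts, which says nothing about stability. The EBSeq calls were in part other transcripts, with 640 of the 906 R-PZQ and 346 of the 644 S-PZQ calls of DESeq among them. With a replicate block 868 and 607 passed, and 18 of the R-PZQ against S-PZQ differences, 17 of them among the 24. The correlation of residuals was highest with the same-numbered vehicle for 1 of 8 treated libraries. No pairing by number was seen in this way, but the called transcripts used were listed by an unpaired test, so pairing cannot be excluded. The 24 differences were 25 in DESeq2 and 18 to 28 with 1 library left out. The 179 shared calls became 81 in edgeR, 153 in EBSeq, 47 under 0.01 and 52, 52, 61, 46, 38 and 48 with split vehicles, where each group has fewer samples. The correlation of 0.931 was 0.969 in edgeR, 0.882 without 1 transcript, and 0.811, 0.719, 0.802, 0.718, 0.644 and 0.712 with split vehicles, where no vehicle library is shared but the transcripts were called with all 4. The 2 lists called under R-PZQ became 1 in edgeR, 0 in EBSeq, 1 under 0.01 and 0 to 2 with 1 library left out, and the 2 under S-PZQ became 1, 2, 1 and 1 to 2, and 0 with depth; the cause was not tested. Rises minus falls under R-PZQ changed sign under 0.01 for heat shock and chaperones (2), tegument (-2), lipid transport and metabolism (-2) and solute carriers (1), for lipid transport also without R-PZQ replicate 2 (-1), vehicle replicate 2 (-1) and vehicle replicate 3 (-2), and for solute carriers without vehicle replicate 2 (1). In EBSeq the sign changed for heat shock (2), tegument (-2), lipid transport (-3), solute carriers (1), the female list (-3), ribosomal proteins (1), proteasome (2) and neuronal signalling (4), and under S-PZQ for proteasome (7); the cause was not tested. Of 1357 values of 97 named transcripts, 1142 kept direction and side of the threshold, 215 missed it and 0 reversed. The edgeR table listed 40 of the 47 named R-PZQ transcripts and 33 of the 40 named S-PZQ ones, and EBSeq 33 and 20. Those not listed there were left out of the 1357 values instead of being counted as missed. Naming also required the same direction in each table, so values from these tables could only count as kept. In the refits, 31 of 47 (R-PZQ) and 24 of 40 (S-PZQ) passed with any 1 library left out. Of the others, 1 and 3 missed the threshold in the refit with all libraries too. Called transcripts had a mean of at least 152.56 or 308.54 in the DESeq and 41.97 or 52.59 in the edgeR tables, and whether depth set these limits was not tested.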

Other observations

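The bound on the transcripts listed under R-PZQ and in no S-PZQ table was planned before, its second part was chosen after the result was seen, and the tests on neighbours and abundance were planned before. All transcripts in the next paragraph were chosen after their values were seen.

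Among the S-PZQ calls in no R-PZQ table, the 7 farthest beyond their bound in standard errors were all falls. Junctophilin (Smp_084090), which ties the surface membrane to internal calcium stores in muscle, had a log2 change of -0.81, where a change beyond 1.22-fold under R-PZQ would have been listed. The saposin (Smp_130100) had -1.09 with a bound of 1.33-fold, paramyosin (Smp_021920.1), a thick filament protein, had -0.63, Smp_035210, of unknown product, had -0.55, and a PUR-alpha-like protein (Smp_042300.1) had -0.65. A myosin regulatory light chain (Smp_132670.1) had -0.46 with a bound of 1.16-fold and CaBP2 (Smp_025390) -2.23 with a bound of 2.08-fold. Of 451 S-PZQ calls in no R-PZQ table, 39 (8.65%) lay beyond their bound by more than their 95% error, 38 of them falls and 7 of them ribosomal protein transcripts, and no gene group was tested among them. The bounds take the spread from the other comparison and assume that the transcript was tested there, and calls are picked for large changes, so these values are no test of the difference.

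Further transcripts that differed between the forms in the direct test had known products. The chromatin enzyme SETDB1 (Smp_043580) had a log2 R over S ratio of 0.82, a second tubulin beta (Smp_164480) 0.80, ubiquitin 1 (Smp_123260) 0.79 and a LIM-binding protein (Smp_149020) 0.54. Lower with R-PZQ were flightless-I (Smp_165930) at -0.88, a septate junction protein (Smp_176350) at -0.74, a tyrosine kinase (Smp_136550) at -0.63 and pericentrin (Smp_051510) at -0.42.

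One hypothesis was that S-PZQ changed the transcripts found under R-PZQ alone by as much, and that these missed the threshold by their spread. For 57 of 617 such transcripts (9.24%) the R-PZQ change lay beyond what could have stayed unlisted under S-PZQ by more than its 95% error, above the limit of 5% set before, with HspB1 (Smp_049240), Smp_186020, Smp_049250, early growth response (Smp_094930) and synaptotagmin (Smp_150350) among the highest. That limit was wrong, because these transcripts were picked for large R-PZQ changes and the spread was borrowed, so the hypothesis stays open. For the other 560 a change of equal size and no change under S-PZQ cannot be told apart, since the S-PZQ values of unlisted transcripts were not analysed here.

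Another hypothesis was that neighbouring genes change together. Among 74 pairs of called neighbours under R-PZQ, 45 (60.8%) had the same direction, against 50.1% in 10000 shuffles (permutation p = 0.0449), which is consistent with it. Among 43 pairs under S-PZQ, 34 (79.1%) did, against 68.0% (permutation p = 0.0754), which leaves it open. A last hypothesis was that falls lie in more abundant transcripts than rises. The median mean level of the falls was 2.27 times that of the rises under S-PZQ (3290 and 1450, permutation p = 1e-05, the smallest the shuffles can give) and 1.22 times under R-PZQ (1369 and 1124, permutation p = 0.0104), which is consistent with it. Whether depth or the detection of abundant transcripts stands behind this was not tested.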
